A study of Brassica napus with 6 samples.

How the data were processed

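RNA was measured by sequencing in seeds of oilseed rape (Brassica napus), an allotetraploid crop that carries an A and a C subgenome. The 6 libraries came from seeds taken 30, 40 and 50 days after flowering from control plants and from plants under drought stress that began at the start of flowering. Each treatment had 1 library per day. Per the labels' protocols, the plants grew under a rain shelter, RNA was extracted with Trizol, and paired reads of 100 bases were sequenced on an Illumina HiSeq instrument. The growth label speaks of 6 lines, and the line or lines behind each library are not given in the labels. Nothing in the labels says that several plants were pooled, or that any library was repeated.

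The authors deposited a table of raw counts per gene for all 6 libraries with a length per gene. They also deposited 1 file per library of FPKM values, in which fragment counts are scaled by transcript length and library size. The submitters' processing notes name Cufflinks, with no version and no role. The aligner, the counting tool, the genome build, the handling of reads that match several places and the use of strand are not given in the sources used here. Of the deposited counts, the values were whole numbers whose totals ran from 10314859 reads in the drought library of day 40 to 16177156 in that of day 30. The FPKM files give no unit in their headers. The deposited values were read as FPKM because Cufflinks is named, because they were never 0 where the count was above 0, and because they followed count per gene length only in rough proportion. The scaling total that the FPKM imply was 1.08 and 1.09 times the count total at day 30 in control and drought. It was 0.930 and 0.671 times at day 40, and 0.782 and 0.765 times at day 50. The authors' FPKM thus carry a scaling that differs from division by the count total, and they were used only as an alternative.

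The table holds 72611 genes. Of these, 32976 have an ID that begins with BnaA and 35737 one that begins with BnaC, which in this naming scheme stand for the A and C subgenomes. A further 225 are unplaced, and 3673 carry the name Cole_newGene, taken here as new gene models. The files do not pair the IDs with gene names, and 0 of the IDs matched the RefSeq gene table of the Da-Ae assembly. The functional gene lists fixed before the data were examined could therefore not be used, and few IDs are printed. By the rule fixed for that case these are the 2 genes with the largest rise and the 2 with the largest fall from day 30 to day 50 among called genes of at least 20 CPM, and the gene of highest mean CPM. No gene met the rule for the drought test, which asked for a mean of at least 5 CPM. The single gene called there is named because it is the only one, a choice made after its values were seen. Near-identical A and C copies can share reads, so the value of any single gene is uncertain to that extent. No genome was used here, and coordinates and exon positions are not reported.

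Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 46483 genes, and libraries were scaled by the trimmed mean of M values (TMM). A quasi-likelihood model with terms for day and treatment was fitted to all 6 libraries, with a Benjamini-Hochberg threshold of 0.05 and two-sided tests. It left 2 residual degrees of freedom per gene. With no replicate of a treatment on a day, the spread in this model is the difference of the drought change between days, and nothing shows that it reflects separate plants. A change seen on 1 day only adds to that spread and is not called. For a single day no p-value is given. The log2 ratio of drought to control was taken with a prior of 0.5 reads per library, and genes at least 2-fold apart were counted among those with a pair mean of at least 5 CPM. Correlations across genes used genes with a mean of at least 5 CPM over the 6 libraries, 27499 in all, and genes are not independent replicates. For correlations and fold classes, the control change set beside a day's drought change was taken between the other 2 control libraries. No library was thus shared there.

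The scripts were tested on simulated data. For the drought test on 45387 genes, 100% of 100 genes planted at 8-fold and 15% of 100 planted at 2-fold were recovered, and 0.0243% of unchanged genes were called. For day 50 against day 30 on 45399 genes the shares were 99%, 5% and 0.0243%. In both, the planted genes had a mean of at least 5 CPM, and both folds were planted together, which eases the adjusted threshold. In the simulation of day 50 against day 30 only the planted genes changed, whereas 9450 of 46483 genes were called in the data. The adjusted threshold was therefore stricter in that simulation, and its 5% does not describe the recovery in the data. For drought the planted fold was the same on all 3 days. The shares therefore do not extend to genes of fewer reads or to drought changes that differ between days. A planted shift of 0.3 along the control time change was recovered as 29.7% of that change and an absent one as -0.212%. Alternatives were other scaling factors, no filter, DESeq2 1.42.0, limma 3.58.1 with voom, models with 1 term left out, each day left out, other priors and CPM minimums, and the FPKM on the log2(value + 0.1) scale. Removal of a smooth gene length trend from each library, leaving out each library in turn, and correlations over genes that also had a pair mean of at least 5 CPM on the days compared were added after the data were seen. Intervals on shares of counts are exact binomial at 95% and cover counting error only.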

Results

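The data cover seed gene expression in Brassica napus at 30, 40 and 50 days after flowering, in control plants and in plants droughted from the start of flowering. There were 6 libraries, 1 for each treatment and day. The control libraries held 12209126, 13893472 and 14918127 counted reads at days 30, 40 and 50, and the drought libraries 16177156, 10314859 and 15024986. A count was seen for 61730, 59322 and 58544 genes in the control libraries and for 62269, 56614 and 58555 in the drought libraries. With no replicate of any treatment on any day, values for a single day describe the libraries and have no replicate check.

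The most abundant seed transcripts held a larger part of the libraries at days 40 and 50 than at day 30, and drought and control differed in how much. In the control libraries the 10 most abundant genes of each library held 3.17% of counts at day 30, 12.3% at day 40 and 19.4% at day 50. In the drought libraries they held 2.58%, 24.6% and 14.4%. The drought library was therefore below its control at days 30 and 50 and above it at day 40. Counting error was small at this depth, with 95% exact binomial intervals of at most 0.0263 percentage points to either side of a share. These intervals leave out differences between plants, so they do not tie the gaps to drought. The 100 most abundant genes of each library showed the same order, with 11.6%, 23.2% and 34.2% in control and 10.5%, 40.1% and 30.1% in drought (intervals of at most 0.0299 points to either side). The gene of highest mean level, BnaA01g08350D, stood at 2019, 16625 and 32760 CPM in control seeds at days 30, 40 and 50. In drought seeds it stood at 987, 35495 and 26883 CPM.

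**Figure D1:**
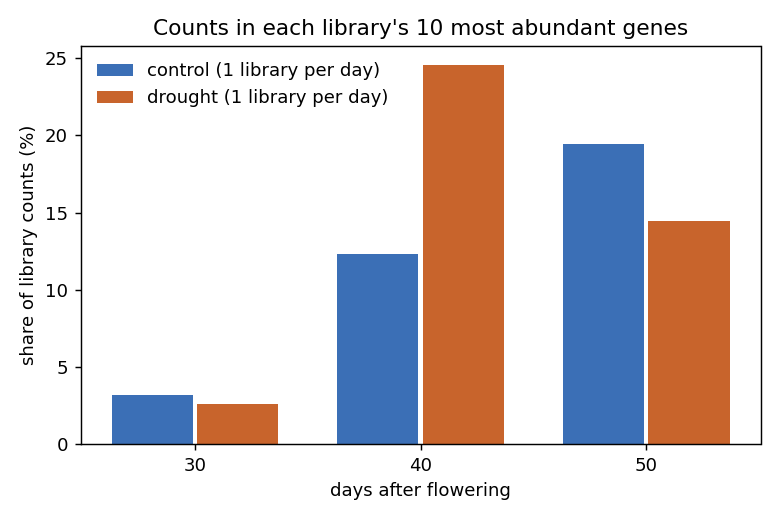
Share of all counts (percent, vertical axis) held by the 10 most abundant genes of each library, by days after flowering, in control and drought seeds with 1 library per bar. The share is higher in drought than in control at day 40 (24.6% against 12.3%) and lower at day 50 (14.4% against 19.4%).

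Whether drought changed the seed transcriptome was asked at each day in turn, and the drought and control libraries stood further apart at each later day. At day 30, 471 of 26790 genes were at least 2-fold apart, 143 higher and 328 lower in drought. At day 40, 2682 of 26606 genes were, with 1612 higher and 1070 lower. At day 50, 5232 of 26670 genes were, with 2676 higher and 2556 lower. The balance of higher and lower genes depended on how genes were chosen. Among the 27499 genes with a mean of at least 5 CPM over all 6 libraries, 319 were higher and 367 lower at day 30, 1713 and 1359 at day 40, and 2286 and 3297 at day 50. Thus 40.95% of the differing genes of day 50 were higher in that set, against 51.1% by the pair mean. By the pair mean, the genes at least 2-fold apart made up 1.76%, 10.1% and 19.6% of the genes, where counting error alone, which leaves out differences between plants, would give 0.0098, 1.59 and 0.180 genes. At least 8-fold differences were found for 2 genes higher and 30 lower at day 30, 56 and 25 at day 40, and 149 and 80 at day 50. The standard deviation of the log2 ratio across genes was 0.38 at day 30, 0.67 at day 40 and 0.88 at day 50.

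The direction of the day 40 difference was kept under some ways of scaling and lost under others. With another set of scaling factors (relative log expression), 1669 genes were higher and 1025 lower, or 61.95% higher. With the gene length trend removed, 60.7% were higher. With counts divided by library totals alone, the median gene of day 40 moved from a log2 ratio of 0.02 to -0.46. The split there became 573 higher and 4421 lower, so that 11.5% of the differing genes were higher instead of 60.1%. With the authors' FPKM the day 40 split was 1266 higher and 1440 lower, or 46.8% higher. The drought change at day 40 also followed gene length. Genes of up to 400 bases had a median log2 ratio of 0.73, genes over 700 and up to 1000 bases 0.30, and genes over 2500 bases -0.29. Across genes, the correlation of the log2 ratio with log2 gene length was -0.361 at day 40, 0.162 at day 30 and 0.0072 at day 50.

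**Figure D2:**
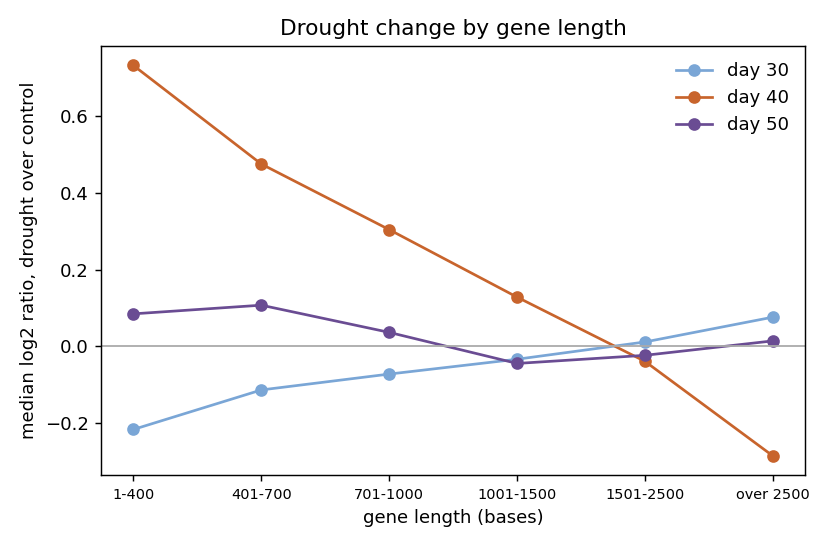
Median log2 ratio of drought over control (vertical axis) for genes grouped by length in bases (horizontal axis), 1 line per day. The line of day 40 runs from 0.73 for genes of up to 400 bases to -0.29 for those over 2500 bases, while those of days 30 and 50 stay between -0.22 and 0.11.

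Over the 3 days together, a drought change of like size was called for a single gene. BnaC09g50960D was higher in drought, with 218, 87 and 29 reads in the drought libraries of days 30, 40 and 50 against 1, 0 and 0 in the control libraries. The line behind each library is not given, so a difference between lines or plants cannot be told apart from drought. The ratio of the summed reads, scaled for depth, was 347, with a 95% counting interval of 61.8 to 13740. Its adjusted p in the edgeR quasi-likelihood test was 0.0291, and the gene with the next smallest adjusted p in that test stood at 0.0877. In all, 1 of 46483 genes was called, higher in drought, and 0 were called lower, with 3339 genes at an unadjusted p under 0.05. The same design called 242 genes with DESeq2, of which 207 were higher and 35 lower in drought, and 134 with limma voom, of which 124 were higher and 10 lower. These tools shared 113 genes, 104 of them higher and 9 lower in drought. Without a filter on low counts edgeR called 467. Without the drought library of day 40, or with the gene length trend removed, edgeR called 0 genes, with 2215 and 3523 genes at an unadjusted p under 0.05. With 1 library left out, the day term alone fits its partner, so that day adds nothing to the drought estimate. Such fits carry the drought changes of the other days only, as do fits with the whole day left out. With day 30, 40 or 50 left out, edgeR called 152, 0 and 25 genes. The adjusted p of BnaC09g50960D was 0.152 in edgeR's test without day 40 and 0.0818 with the length trend removed. Over edgeR with other scaling factors, no filter or no day term, DESeq2 and limma voom, its adjusted p ran from 9.33e-09 to 1. Its log2 fold change was 7.30 without day 40 and 8.09 with the length trend removed, against 8.01 with all libraries and no removal. It ran from 7.01 to 9.36 over these settings and with each day left out, so the fold stayed large where the call was lost.

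The drought changes of days 40 and 50 resembled each other, and that of day 30 resembled neither. Across 27499 genes, the log2 ratios of days 40 and 50 had a Pearson correlation of 0.375 and a Spearman correlation of 0.336. Day 30 correlated with day 40 at -0.0384 and -0.0726, and with day 50 at 0.0520 and 0.0680. These comparisons share no library. At days 40 and 50, 616 genes were at least 2-fold higher in drought on both days and 532 at least 2-fold lower on both. Independent lists would share 142 and 163. A further 157 genes were at least 2-fold apart on both days in opposite directions. On all 3 days, 80 genes were at least 2-fold higher in drought and 17 at least 2-fold lower, 97 in all where independent lists would share 3.83. Of the 80, 67 were also at least 4-fold higher in control seeds at day 50 than at day 30. Of all 27499 genes, 1007 were 4 to 16-fold higher in that control comparison and 604 over 16-fold higher. This comparison shares the control libraries of days 30 and 50 with the drought ratios. A low control value at day 30 raises both it and the drought ratio of that day, so the 67 are no separate evidence. A further 79 genes were 2-fold apart on all 3 days with day 30 opposite to days 40 and 50, against 7 with day 50 opposite and 10 with day 40 opposite. Independent lists would share 3.79, 3.89 and 4.05 in these patterns. The pattern with day 30 opposite thus also passed its value, so an excess over independent lists does not by itself show a like change on all 3 days. Genes entered by their mean over the 6 libraries, which does not ensure reads at day 30.

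Whether the drought change ran along the course of seed development was asked by setting each day's drought change beside the control change between the other 2 days. The grouping by fold was chosen after the data had been seen, while the correlations were planned. At day 40 the genes that differed most between control seeds of day 30 and day 50 also differed most between drought and control. The 604 genes over 16-fold higher in control seeds at day 50 than at day 30 had a median drought log2 ratio of 1.62 at day 40, and 450 of them were at least 2-fold higher in drought. The 250 genes over 16-fold lower in control seeds at day 50 had a median of -1.35, and 142 of them were at least 2-fold lower in drought. The 20831 genes within 2-fold between the control days had a median of -0.01. With the gene length trend removed the first 2 medians were 1.47 and -1.40. Over the 500 and 97 genes of these classes with a mean of at least 5 CPM in the libraries of day 40 itself, they were 1.58 and -0.95. The correlation across 27499 genes was 0.477 (Pearson) and 0.260 (Spearman), and the slope amounted to 22.5% of the control change from day 30 to day 50.

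At the other days the correlations were lower in value, but they are not on one scale. The control change used for day 40 spanned that day, while those for days 30 and 50 were shorter steps that did not. On the first principal component, drought lay at -144 against -147 in control at day 30, 58.0 against -12.4 at day 40 and 159 against 86.6 at day 50. This component was fitted to all 6 libraries, drought included, so it is no independent measure of seed development. Since the correlations are not on one scale, a weaker forward shift at day 50 than at day 40 is not shown. At day 50 the 277 genes over 16-fold higher in control seeds at day 40 than at day 30 had a median drought log2 ratio of 0.92. The 259 genes 4 to 16-fold lower in control had a median of -0.91, and -0.66 over the 62 of them with a mean of at least 5 CPM at day 50. Of the 58 genes over 16-fold lower, 3 reached that level and 19 had no read at day 50, so no drought change was read from them. The correlation at day 50 was 0.106 (Pearson) and 0.0487 (Spearman). At day 30 the correlation with the control change from day 40 to day 50 was 0.0993 and 0.107. There the 49 genes over 16-fold lower in control had a median of -0.51, while 0 of the 35 genes over 16-fold higher reached 5 CPM at day 30. Over genes that also had a mean of at least 5 CPM on the day itself, the Pearson correlations were 0.144, 0.441 and 0.0563 at days 30, 40 and 50. The value of day 50 varied with the choice of genes and libraries: it was 0.324 over genes with a mean of at least 50 CPM and 0.252 with the drought libraries' own time change, against 0.680 and 0.570 at day 40. Differences in these correlations between days were not tested, since each day had 1 library per treatment.

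**Figure D3:**
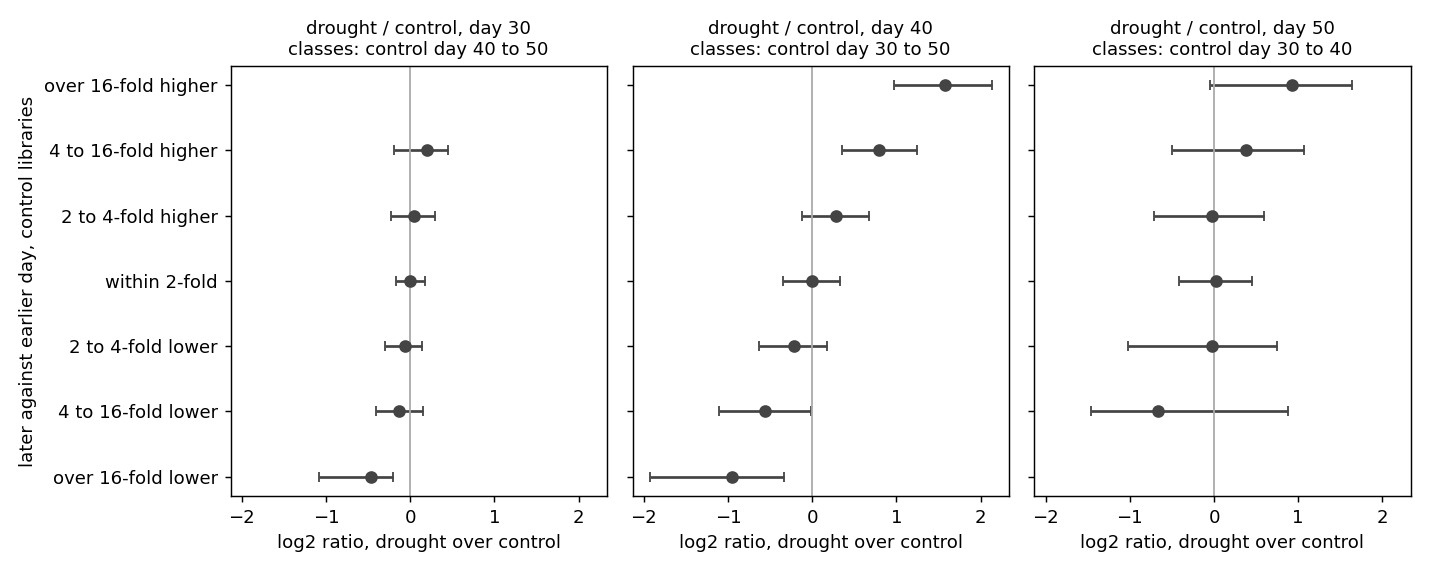
Log2 ratio of drought over control (horizontal axis) at each day, for genes with a mean of at least 5 CPM on that day, grouped by their fold change between the other 2 control libraries (vertical axis, classes under 20 genes left out). Points are medians and bars run from the lower to the upper quartile of genes. At day 40 the medians run from -0.95 for genes over 16-fold lower to 1.58 for genes over 16-fold higher.

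The step in seed age from day 30 to day 50 separated the libraries more than drought did on any day, whereas the step from day 40 to day 50 in control seeds did not exceed drought at day 50. The correlation of log2 CPM between drought and control of the same day was 0.964 at day 30, 0.881 at day 40 and 0.849 at day 50. The control libraries of days 30 and 50 correlated at 0.516, and the drought libraries of these days at 0.340. The control libraries of days 40 and 50 correlated at 0.853, and the drought libraries of these days at 0.773. The drought library of day 40 correlated with the control library of day 50 at 0.888. On the first principal component, which held 74.8% of the variance, the control libraries lay at -147, -12.4 and 86.6 and the drought libraries at -144, 58.0 and 159. The second, with 14.1%, set the drought library of day 50 at 80.7, and the control library of that day at -24.1.

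**Figure D4:**
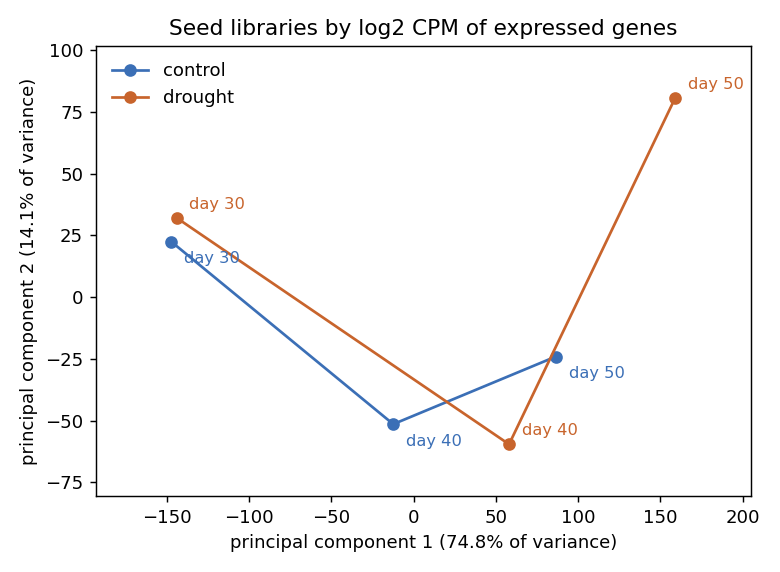
The 6 libraries on the first 2 principal components of log2 CPM over genes with a mean of at least 5 CPM (component scores, with the share of variance on each axis). Lines join the days of a treatment. At day 40 the drought library lies at 58.0 on the horizontal axis and the control library at -12.4, and at day 50 they lie at 159 and 86.6.

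Gene expression changed widely between days, as tested over both treatments with edgeR's quasi-likelihood test. From day 30 to day 50, 9450 of 46483 genes changed, of which 4719 rose and 4731 fell. The change was over 4-fold for 2764 genes that rose and 2842 that fell, and over 16-fold for 1018 and 733. Among the genes that rose, 3215 were higher at each later day in both treatments. Among those that fell, 3444 were lower at each later day in both. From day 30 to day 40, 2988 genes changed, 2013 upwards and 975 downwards. Of these, 2709 were also called from day 30 to day 50 in the same direction. Without a filter on low counts, 3169 rose and 2818 fell over that step. From day 40 to day 50, 670 genes changed, of which 344 rose and 326 fell. For this step limma voom called 208 genes that rose and 509 that fell, and edgeR without the control library of day 50 called 1473 and 2100. These counts depended on single libraries. From day 30 to day 50, 3913 genes were called without the drought library of day 30. From day 30 to day 40, 923 and 1071 were called without the drought libraries of days 30 and 40, and 5935 and 6087 without the control and drought libraries of day 50. From day 40 to day 50, 1649, 164 and 3573 were called without the control libraries of days 30, 40 and 50, and 1690, 10 and 265 without the drought libraries.

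The largest rises from day 30 to day 50 among called genes of at least 20 CPM belonged to BnaA01g19290D and BnaC01g23250D. BnaA01g19290D had no read in either library of day 30. It reached 20.1 and 62.7 CPM at day 40 and 120 and 283 CPM at day 50, in control and drought. It was at least 2438-fold higher at day 50, against a floor of 3 reads over the libraries of day 30. BnaC01g23250D, also without a read at day 30, stood at 110 and 256 CPM at day 50 and was at least 2215-fold higher against the same floor. The adjusted p-values in edgeR's test were 6.76e-05 for BnaA01g19290D and 7.08e-05 for BnaC01g23250D. The largest falls belonged to BnaC03g45710D and the gene model Cole_newGene_953. BnaC03g45710D went from 278 and 220 CPM at day 30 to 1 read in both libraries of day 50 together, 6279-fold lower with a counting interval of 1127 to 248000. Cole_newGene_953 went from 106 and 47.4 CPM to 2 reads, 927-fold lower with an interval of 256 to 7655. Their adjusted p-values in edgeR's test were 8.34e-05 and 6.76e-05.

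Genes of both subgenomes changed with seed age, and the difference between subgenomes was not tested. From day 30 to day 50, 21.1% of 21453 tested A genes and 19.9% of 22452 tested C genes changed, as did 17.5% of 2490 new gene models. Of the A genes 2176 rose and 2347 fell, and of the C genes 2275 rose and 2201 fell. On the chromosomes named in the IDs, the share of tested genes that changed ran from 19.1% on C09 to 21.9% on A01. The share of all counts that came from A genes was 48.1%, 49.5% and 50.96% in control seeds at days 30, 40 and 50, and 47.6%, 51.5% and 49.1% in drought seeds, with counting intervals of at most 0.0305 points to either side. As a share of A and C counts outside the 1000 most abundant genes, A genes held 48.99%, 48.4% and 48.7% in control and 48.6%, 48.6% and 48.3% in drought. At each day the median drought log2 ratio of A genes lay within 0.03 of 0, and that of C genes within 0.01 of 0. Differences between treatments in these shares and medians were not tested.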

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

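The tests of gene length in seed development and of fragment size, and that of a later harvest stage or wrong day label, were chosen after the results they bear on had been seen. The other tests were set before their values were known.

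Several library-wide values differed between drought and control in opposite directions on different days, with 1 library per treatment and day, so the difference between days was not tested. The share of counts in each library's 10 most abundant genes differed by -0.584 percentage points at day 30, 12.3 at day 40 and -4.98 at day 50, drought minus control. For the 100 most abundant genes the differences were -1.12, 16.9 and -4.07 points. For the share of counts from A genes they were -0.494, 1.99 and -1.82 points. Outside the 1000 most abundant genes, the A share of A and C counts was 48.4% in control and 48.6% in drought at day 40, and 48.7% and 48.3% at day 50, so on these days the differences lay mainly in abundant genes. At day 30 it was 48.99% and 48.65%. For BnaA01g08350D they were -1030, 18900 and -5880 CPM.

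The drought profile of day 40 lay further along the control course of development than the control profile of the same day, with a correlation of 0.477 across genes. A trend with gene length as the whole cause is argued against, since the correlation was 0.534 after that trend was removed from every library. Unequal depth as the whole cause is argued against too: with every library thinned to 10314859 reads and the 1000 most abundant genes left out, it was 0.439. The correlation weighs all genes alike, so leaving out the abundant genes could hardly move it. The value therefore decides little about a few abundant genes as the cause. A later harvest stage or a wrong day label cannot be told apart from an effect of drought on the pace of seed maturation, because 1 library carries both. That library correlated at 0.888 with control day 50 and at 0.881 with control day 40, and faster maturation under drought remains an untested hypothesis.

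At day 40 short genes were higher and long genes lower in drought, with a correlation of -0.361 between the drought log2 ratio and log2 gene length. A lasting change in seed development as the source is argued against, since the control change from day 30 to day 50 correlated with length at only 0.0538. The control steps from day 30 to 40 and from day 40 to 50 correlated with length at 0.0116 and 0.0879. Those of the drought libraries did so at -0.224 and 0.304, so the trend lay mainly in the drought library of day 40. A brief trend between the days sampled is not excluded. The correlation of the day 40 drought log2 ratio with length was -0.362 with the 1000 most abundant genes left out. It weighs all genes alike, so leaving these out could hardly move it, and the value decides little about abundant genes. Shorter fragments in the drought library of day 40 may be part of the cause: the authors' FPKM, whose length term can follow fragment size, gave -0.233, between the bounds set for a verdict. The length term in those FPKM, as the ratio of short to long genes, was 0.325 for that library and 0.188 to 0.232 for the others, while RNA quality was not measured here.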

How the results depend on the processing

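Removal of the gene length trend, a pair mean of at least 5 CPM for the correlations and leaving out each library in turn were chosen after the data had been seen; the other alternatives were set before. Of the alternative values, 68 kept their size within the bound set for them and 97 did not, and the cause was not tested. For counts the bound was a ratio of 1.5. For correlations it was the reach to either side of a 95% interval that took the 27499 genes as independent, which they are not. Another CPM minimum also changes the genes counted, so the 97 is not a measure of instability. In edgeR, other scaling factors gave like counts: 1 gene for drought, 2973 and 2997 from day 30 to 40, 661 and 646 from day 40 to 50, and 9449 under both from day 30 to 50. Without a filter on low counts, 467 genes changed with drought (365 higher, 102 lower), 5987 from day 30 to 40 and 3498 from day 40 to 50. DESeq2 called 242 for drought (207 higher, 35 lower) and 2213 from day 40 to 50, and limma voom 134 for drought (124 higher, 10 lower). For drought, 0 were called without the day term and 0 with the length trend removed, with 575 and 3523 at an unadjusted p under 0.05. Without the treatment term, 1301 changed from day 30 to 40 and 0 from day 40 to 50, the latter with 7308 at an unadjusted p under 0.05. Leaving out 1 library or 1 day gave 0 to 251 genes for drought (0 to 175 higher, 0 to 76 lower). Leaving out 1 library gave 923 to 6087 from day 30 to 40, 10 to 3573 from day 40 to 50 and 3913 to 10896 from day 30 to 50. In such fits a library that stands alone is assumed to vary like the others. For the drought test that library adds nothing to the estimate, so leaving out 1 library carries the same drought changes as leaving out its day. With a pair mean of at least 1 CPM, the 2-fold counts (higher and lower in drought) were 895 and 1650 at day 30, 3686 and 3198 at day 40, and 5272 and 5504 at day 50. With at least 20 CPM they were 27 and 49, 723 and 308, and 1099 and 860. The authors' FPKM gave 215 higher at day 30, and total counts 573 higher and 4421 lower at day 40. The correlation of the drought changes of days 30 and 40 was 0.00305 at a mean of at least 1 CPM, -0.0563 at 50 CPM, -0.0726 as Spearman's, 0.0216 with the length trend removed and -0.0724 with a prior of 5 reads. For days 40 and 50 it was 0.274, 0.553, 0.336 and 0.405 under the first 4 of these. For days 30 and 50 it was 0.0689 at 50 CPM and 0.0680 as Spearman's. The correlation with the control time change was 0.0704 at 1 CPM, 0.0837 at 50 CPM and 0.0874 with the length trend removed at day 30. At day 40 it was 0.370 at 1 CPM, 0.680 at 50 CPM, 0.260 as Spearman's and 0.534 with the length trend removed. At day 50 it was 0.0365 at 1 CPM, 0.324 at 50 CPM and 0.0487 as Spearman's. With a pair mean of at least 5 CPM on the days compared, the correlations between days were -0.0633 for days 30 and 40 and 0.0861 for days 30 and 50, and those with the control time change were 0.144, 0.441 and 0.0563 at days 30, 40 and 50. With the drought libraries' own time change the latter were 0.140, 0.570 and 0.252 at days 30, 40 and 50. The planned gene list medians and tests were not run, since the IDs could not be paired with names. Depth limits genes of few reads: 3 reads stood for 0.143 to 0.384 CPM across the libraries. The day term already pairs the drought and control library of each day.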

Other observations

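The tests in this part were set before their values were known, but the gene groups in it were formed after the data had been seen. Genes within 2-fold between the other 2 control days, called steady here, and the other genes were counted apart. The difference between these groups was not tested. Of the 23628 genes within 2-fold between control days 30 and 40, 4011, or 16.98%, were at least 2-fold apart in drought at day 50, with 1588 higher and 2423 lower. Of the other 3871 genes 1572, or 40.6%, were, with 698 higher and 874 lower. At day 30, 296 of 24006 genes steady between control days 40 and 50, or 1.23%, were at least 2-fold apart, and 390 of the other 3493, or 11.2%. Over genes with a mean of at least 5 CPM on the day itself, the shares were 15.8% and 38.4% at day 50 and 0.784% and 4.99% at day 30. Counting error alone would give 7.29 of the steady genes of day 50, chosen by their mean over 6 libraries, but it leaves out differences between plants, so the comparison decides nothing about drought.

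Some chromosomes, and at day 40 the new gene models, lay slightly apart from the other genes. New gene models with a mean of at least 5 CPM, 836 in number, had a median drought log2 ratio of -0.12 at day 40, below all 10000 random lists of the same size matched on expression. At days 30 and 50 their medians lay inside the central 95% of such lists, at percentiles 65.6 and 66.0. Among 19 chromosomes, 6 lay outside the central 95% of the random lists at day 30, 4 at day 40 and 3 at day 50. The chromosome medians ran only from -0.05 to 0.04 at day 30, from -0.09 (C02) to 0.06 (A02) at day 40 and from -0.05 to 0.05 at day 50. The lists were not matched on gene length, which the drought change of day 40 followed.

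Genes present in one treatment and near absent in the other were few. Since the line behind each library is not given, a difference between lines or plants cannot be told apart from drought in them. With at most 3 reads over the libraries of one treatment and at least 10 in each of the other, 5 genes were near absent in control and 1 in drought, BnaC09g50960D among the former and BnaA05g28580D the latter, both named after their values were seen. Of the 10 splits of the 6 libraries in 3 and 3, 4 gave at least 6 such genes, the real one included, and the highest other split gave 149. That split set both libraries of day 30 and the control library of day 40 against the rest, so it follows the structure by seed age, and 10 splits are too few for a share under 0.05. Only 4 of the 10 splits part the libraries of all 3 days as treatment does, and these gave 6 (the real one), 4, 3 and 6 such genes. For the drought test over the 3 days, 1 of the 10 splits called at least 1 gene, the real one, and the highest other split called 0, again with too few splits for a share under 0.05.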
